A study of Arabidopsis thaliana with 12 samples.

How the data were processed

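The study measured messenger RNA by RNA sequencing in 12 libraries from 6-day Arabidopsis thaliana seedlings. Wild type (WT) and plants labelled hd2b hd2c were each grown at 22 °C and either kept there (normal) or held at 44 °C for 3 h (heat), per the labels, which gives 4 groups of 3 libraries. Per the labels, total RNA was extracted with Trizol and libraries were made with the Abclonal Fast RNA-seq library kit V2. Per the submitters' processing notes, reads were aligned to the TAIR10 genome with HISAT2 2.1.0 and counted per gene with featureCounts 2.0.3. The strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. Genes that overlap on opposite strands or that have near-identical copies are therefore uncertain.

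The deposited table holds raw counts of reads per gene, whole numbers that were not normalised, in 12 columns named by group and replicate. It has 33330 features, of which 32842 matched a gene of the TAIR10.1 reference annotation. Of these features, 29419 have plain locus identifiers and 3911 carry a numbered suffix. The reference classes 3909 of the suffixed features as pseudogenes, a class that holds most transposable element loci, and 878 of the suffixed features had any count. Suffixed features were kept as separate features, under the identifier in the table. Gene symbols and the order of neighbouring genes come from TAIR10.1, and no coordinates are given because the reads were aligned to a release named differently. The table has 0 features of plastid or mitochondrial genes, so a share of organelle transcripts was not analysed here. It has 4 ribosomal RNA features, which were kept.

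Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its robust quasi-likelihood F test, which is two-sided. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20232 genes. Library sizes were scaled by trimmed mean of M values (TMM) factors, and the CPM values given use them. A single fit of the 4 groups gave 5 comparisons, namely heat in WT, heat in hd2b hd2c, genotype at normal temperature, genotype after heat and the genotype by heat interaction. The common dispersion was 0.0236. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called when its adjusted p was under 0.05. Log2 fold changes are given with a standard error (SE) derived from the F test. It is the absolute log2 fold change divided by the square root of F, and is approximate for genes with few counts. Each group mean is over n = 3 libraries. The wording "rose", "fell" and "changed" is kept for called genes.

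Gene lists were fixed before the data were examined, and 24 of them had at least 4 tested members and were tested as sets. Most were fixed by symbol and locus. The lists of cytosolic ribosomal proteins and of transposable element genes were instead made by matching words in the annotation. Either can therefore hold other genes, such as protein-coding genes whose annotation names a transposon. The histone deacetylase list leaves out HD2B and HD2C. The set test was camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison. Each set test was repeated with an estimated correlation and with fry, which asks whether a list moves on balance one way and does not compare it with other genes. Members of each list were also counted with p-values adjusted over the list alone. Of the fixed members, 1 was dropped because its symbol belongs to another locus. A class of suffixed pseudogene loci and lists of DNA damage response genes and of rapid touch and wound response genes were added after the data had been seen.

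Genes are named by a rule fixed before the data were examined. In each comparison the rule takes the 6 largest positive and the 6 largest negative log2 fold changes among called genes with a mean of at least 5 CPM in a compared group. Outside the interaction it also asks that all 3 libraries of one group lie above all 3 of the other. It adds HD2B and HD2C, up to 4 called members, by smallest adjusted p, of every list that camera called, and the called members of the lists of RNA-directed DNA methylation, histone deacetylase, ONSEN, small heat shock protein and heat stress transcription factor genes. A gene without a symbol in the annotation is given by its locus. Genes outside the rule are said to be chosen after their values were seen.

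For a gene with 0 counts in a whole group, the fold is given against a floor of 3 counts over the group and written as at least that large. For a gene with 1 to 3 counts in a group, the ratio is given with an exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of counts between groups of 3 libraries were compared by an exact two-sided permutation test, whose smallest possible p is 0.1.

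The alternatives were DESeq2 1.42.0, relative log expression (RLE) factors, library totals without scaling factors, upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, fits of only the groups compared, the replicate number as a block, an adjusted p under 0.01, a fold of at least 2, and leaving out each library in turn. Leaving out the ribosomal RNA features, leaving out libraries that are not part of a comparison, and an estimated correlation for lists that passed under an alternative alone, were chosen after seeing the data. The alternative of counting only nuclear genes was not run, because the table holds no others.

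The fitting code was tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold, drawn from the real means and library sizes. Of 100 genes changed 2-fold, 94 were recovered for heat in WT (19428 genes fitted), 87 for heat in hd2b hd2c (19523 genes), 93 for genotype at normal temperature (20019 genes) and 89 for genotype after heat (20013 genes). For the interaction 64 of 100 were recovered (20013 genes). Of 100 genes changed 4-fold, 99 were recovered for heat in WT and 100 in each of the other 4 comparisons. Between 5 and 11 unchanged genes were called in a comparison. Changed genes were drawn only from those above a minimum mean CPM, and counts were drawn with the dispersions of the fit. The simulated heat data held no other heat effect and no library that stood apart. The recovery therefore need not hold for the real libraries. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

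Total counts ranged from 7737285 to 24030931 per library. No library was left out. Read-level files, splicing, small RNAs and chromatin marks were not analysed here.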

Results

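RNA was sequenced from 6-day Arabidopsis thaliana seedlings of wild type (WT) and of plants labelled hd2b hd2c, named for lesions in HD2B and HD2C, which encode plant-specific histone deacetylases. Seedlings stayed at 22 °C (normal) or were held at 44 °C for 3 h (heat), which gave 4 groups of 3 libraries. The series concerns HD2B, HD2C and Argonaute 4 (AGO4) in heat tolerance and heterochromatin, and the comparisons ask how transcripts differed with heat and with genotype. Total gene counts were 22083518, 10443494 and 17472584 in WT normal replicates 1 to 3 and 20784014, 19124529 and 22987275 in WT heat. They were 16844188, 18748086 and 17431810 in hd2b hd2c normal and 24030931, 7737285 and 23519653 in hd2b hd2c heat. The library hd2b hd2c heat replicate 2 stood apart, with 11.2% of its counts from ribosomal RNA (0.734% to 5.02% in the other 11) and 34.1% from its 10 most abundant genes (16.3% to 24.8% in the other heat libraries). Its mean Spearman correlation with its group was 0.961, against 0.973 to 0.99 for the other 11 libraries. No pair of replicates was within sampling noise, since the chi-square per gene lay between 7.8 and 151. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples.

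HD2B (AT5G22650, chromosome 5) was lower in the libraries labelled hd2b hd2c at both temperatures, and HD2C (AT5G03740, chromosome 5) was higher. HD2B fell from 40.0 ± 3.00 CPM in WT to 23.8 ± 2.76 at normal temperature (mean ± SD, n = 3 each), a log2 fold change of −0.75 (SE 0.133, adjusted p 0.00203 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). After heat it fell from 85.8 ± 4.97 to 18.6 ± 4.75 CPM, or −2.15 (SE 0.145, adjusted p 2.48e-09). HD2C rose from 37.3 ± 2.40 CPM in WT to 98.1 ± 6.97 at normal temperature, or 1.40 (SE 0.114, adjusted p 7.87e-08), and from 149 ± 4.69 to 324 ± 30.2 after heat, or 1.12 (SE 0.113, adjusted p 2.77e-06). In all 6 libraries labelled hd2b hd2c, HD2C was above each WT library at the same temperature, which loss of its transcript would not give. An insertion allele can leave reads from a part of the gene, so HD2C counts neither contradict the label nor bear it out. The groups are therefore called the libraries labelled hd2b hd2c, and directions drawn from them rest on the label. Counts per gene do not show whether a transcript is complete, and protein was not measured. In WT, heat raised HD2B by 1.1 (SE 0.133), which turned to −0.43 with library totals in place of TMM factors, and HD2C by 2.00 (SE 0.116). In the libraries labelled hd2b hd2c HD2C rose by 1.72 (SE 0.114), while HD2B did not pass (−0.30, SE 0.142, adjusted p 0.0747). The heat effect differed between genotypes for HD2B (interaction −1.40, SE 0.195, adjusted p 0.000928) and was not shown to differ for HD2C (−0.27, SE 0.158, adjusted p 0.659). With library totals in place of TMM factors the HD2B difference at normal temperature did not pass (−0.69, adjusted p 0.396).

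**Figure D1:**
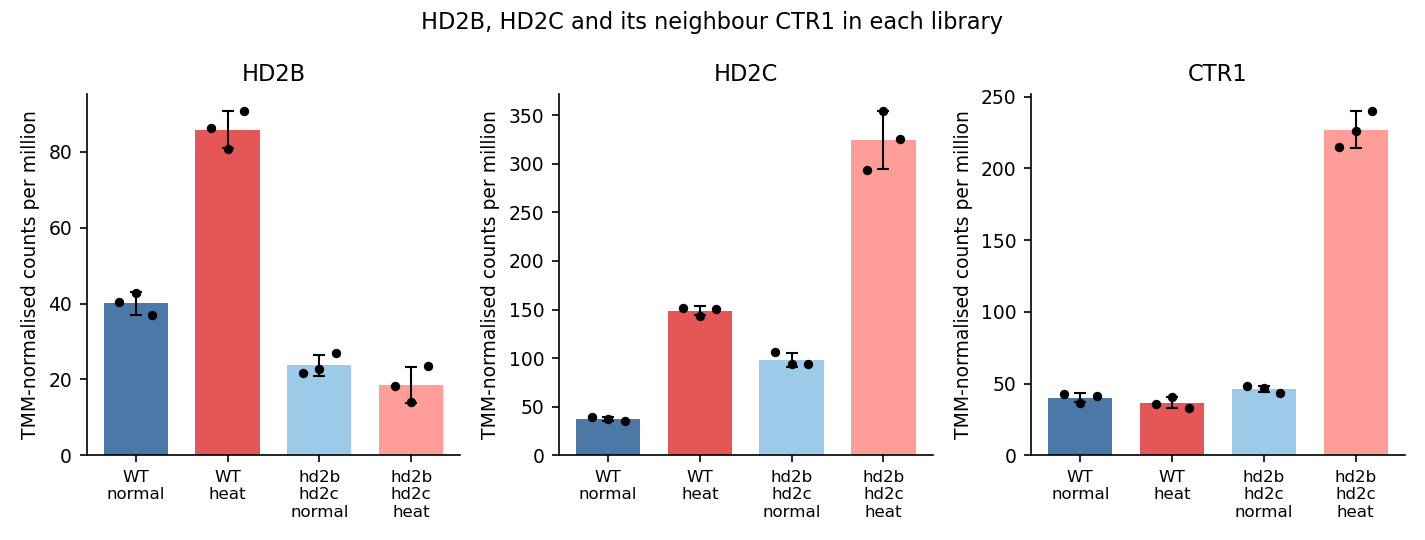
TMM-normalised CPM of HD2B, HD2C and CTR1 in each library (points), with group means (bars) and SD (n = 3). HD2C lies higher in the 6 libraries labelled hd2b hd2c than in WT at each temperature, and CTR1 rises to 227 in hd2b hd2c heat.

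Genes next to HD2C were also higher in the libraries labelled hd2b hd2c. CTR1, a kinase that represses ethylene signalling and the next tested gene on one side, rose from 36.8 ± 3.82 CPM in WT to 227 ± 12.7 after heat, or 2.63 (SE 0.118, adjusted p 6.69e-13). At normal temperature CTR1 did not pass (0.19, adjusted p 0.488), and its interaction was 2.43 (SE 0.16, adjusted p 4.17e-09). HSFA3, a heat stress transcription factor gene on the far side of CTR1, rose by 1.91 after heat (SE 0.267, adjusted p 0.000241) and did not pass at normal temperature (0.46, adjusted p 0.464), and its interaction did not pass (1.45, adjusted p 0.0941). 4 further neighbours were chosen after their values were seen. AT5G03750, annotated as a ubiquitin ligase and next to HD2C on the other side, had 4 counts in WT heat and 145 in hd2b hd2c heat (5.03, SE 0.708, adjusted p 0.000347), and 0 against 30 at normal temperature. ATCSLA09, a mannan synthase gene beyond it, rose by 0.63 at normal temperature (SE 0.132, adjusted p 0.0085) and did not pass after heat (0.26, adjusted p 0.351). Beside HD2B, emb1211, a gene of chloroplast biogenesis, fell by 0.46 at normal temperature (SE 0.112, adjusted p 0.0229), and AT5G22700 rose by 0.68 after heat (SE 0.175, adjusted p 0.0356).

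**Figure D2:**
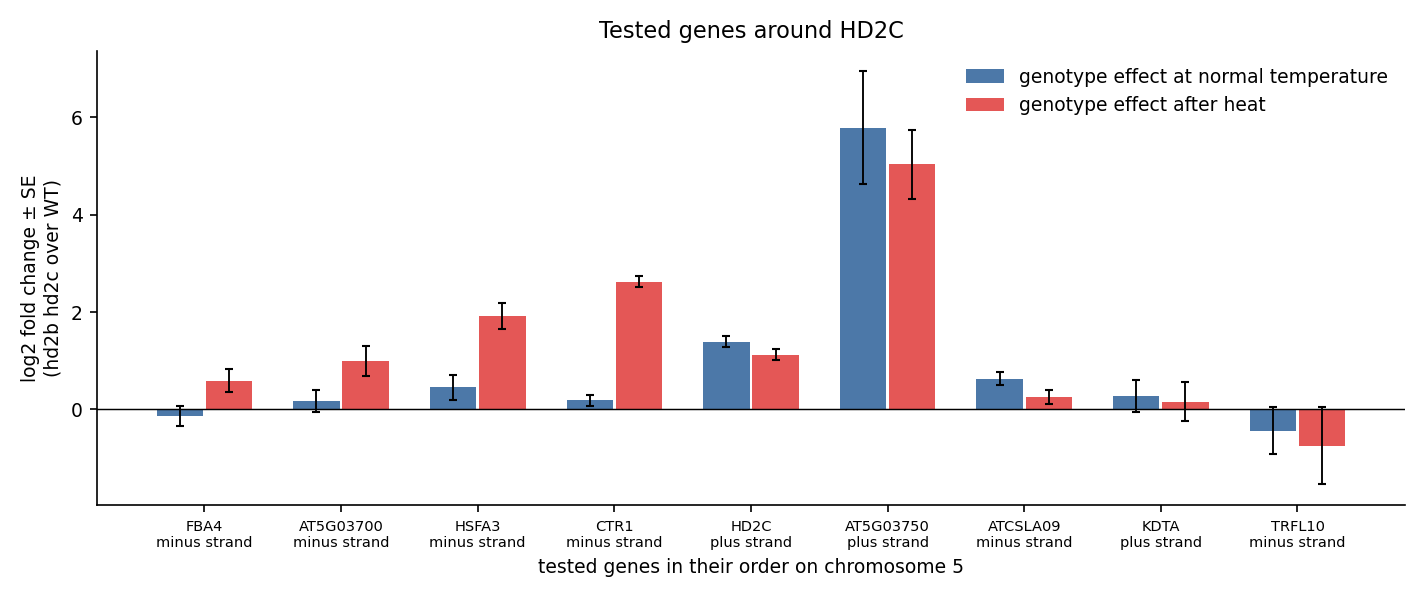
Log2 fold change (± SE, n = 3 per group) of the libraries labelled hd2b hd2c over WT for the tested genes around HD2C, in their order on chromosome 5, at normal temperature and after heat. HD2C is higher in both comparisons (1.40 and 1.12) and CTR1 after heat (2.63). Each SE is derived from the F test.

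All 17 small heat shock protein and all 26 nuclear photosynthesis genes tested rose in WT after heat, and all 7 root hair genes fell. Small heat shock proteins, chaperones that hold unfolded proteins, had the largest increases. HSP17.6II rose by 12.76 (SE 0.277), HSP17.4 by 12.50 (SE 0.3), HSP17.8 by 12.45 (SE 0.304), HSP23.6-MITO by 12.33 (SE 0.352), HSP17.6A by 12.32 (SE 0.354) and ATHSP22.0 by 12.10 (SE 0.516) on the log2 scale. All 17 members of that list rose, with a median of 11.45, down to HSP14.7 (1.68) and HSP15.4 (1.06, and −0.48 with library totals only). Of 28 genes for HSP70, HSP90, HSP100 and co-chaperones 27 rose (median 4.31), among them Hsp70b (10.14, SE 0.229), ROF2 (8.40), HSA32 (7.18) and MTHSC70-2 (6.98). All 13 oxidative stress genes rose (median 2.65), with the ascorbate peroxidase APX2 at 10.24 (SE 0.265), the galactinol synthase GolS1 at 8.00 (SE 0.195), the zinc finger factor RHL41 at 5.16 and the catalase CAT2 at 3.96. All 26 nuclear photosynthesis genes rose (median 2.70), including the light-harvesting genes LHCB2.1 (5.61, SE 0.292) and LHCB2.2 (5.52), PSBO2 (3.32) and Rubisco activase RCA (3.8, SE 0.227). Among 21 heat stress transcription factor genes 9 rose and 3 fell. AT-HSFA7B (10.44), HSFA2 (10.15, SE 0.279), MBF1C (8.54), HSFA7A (7.02, SE 0.174), DREB2A (6.44) and HSFB2A (5.84) rose, and HSFC1 (−2.41), AT-HSFA5 (−1.53) and RHA1 (−1.44) fell, while HSFA1E, which also rose, turned to −0.44 with library totals only. Abscisic acid and dehydration genes rose in 14 of 19 cases (median 1.3) and fell in none, including the biosynthesis gene NCED3 (4.30, SE 0.179) and the phosphatase genes HAI2 (4.06), HAI1 (3.73) and ABI1 (1.93). Genes that fell included AT3G23470, annotated as a cyclopropane fatty acid synthase, with 0 counts after heat and 434 before (at least 62.8-fold lower), and the late embryogenesis abundant gene AT5G60530, with 0 against 416 (at least 60.2-fold lower). TAS1C, a source of trans-acting small RNAs, had 2 counts after heat (141-fold lower, 95% interval 38.8 to 1160). TAS1A (−5.68, SE 0.334), the pseudogene AT2G07600 (−6.52, SE 0.479) and the camalexin gene CYP71A13 (−5.58, SE 0.555) fell as well. In all, 6269 genes rose and 7046 fell of 20232 tested by edgeR's quasi-likelihood test (3626 and 4776 at least 2-fold), so 47.1% of calls were increases. The median of all genes was −0.14, and changes are relative to TMM scaling. On library totals only that median was −1.67 and the calls were 1031 higher and 16005 lower (6.1% higher), and with upper-quartile factors it was −0.39 with 5016 higher and 8623 lower (36.8%).

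Genes of histone deacetylases, of RNA-directed DNA methylation (RdDM) and of transposable elements were counted in WT with heat by single-gene calls. Of 12 genes in the histone deacetylase list, which leaves out HD2B and HD2C, 7 rose and none fell (median 0.59). The camera call of the list was lost with an estimated correlation (adjusted p = 0.117). Those that rose were HDA08 (2.43, SE 0.114), HDA6 (1.12), HD1 (0.91), HDA2 (0.89), SRT2 (0.86), HDA3 (0.72) and HDA15 (0.47), and with library totals only all but HDA08 turned negative and so did the median of the list (−0.95). AGO4, which binds small RNAs that direct DNA methylation, rose by 1.14 (SE 0.147, adjusted p 4.67e-07) and turned to −0.39 with library totals only. Of 26 RdDM genes 7 rose, namely RDM1 (1.75), the RNA polymerase subunit genes NRPD2A (1.2) and NRPD1A (0.77), AGO4, SUVH9 (0.84), CRT1 (0.67) and the methyltransferase gene DRM2 (0.53), and all but RDM1 turned negative with library totals only. The 8 that fell were IDN2 (−2.25), KTF1 (−2.02), CHR38 (−1.97), DCL3 (−0.84), DMS11 (−0.82), HEN1 (−0.60), NRPD1B (−0.46) and CHR40 (8.89-fold lower, 95% interval 2.31 to 75.9). Of 18 genes in the transposable element list, which was matched by annotation words, 11 fell and 1 rose (median −1.12). Those that fell included SADHU1-3 (−2.58), AT3G13030 (−1.97), SADHU4-1 (−1.93) and AT1G79740 (−1.89). The camera call of the list was lost with an estimated correlation (adjusted p = 0.150). Of the heat-responsive retrotransposon ONSEN 2 copies passed the filter and rose, ONSEN5 at least 43.0-fold from 0 counts and ONSEN3 33.8-fold (95% interval 10.8 to 170). All 7 root hair genes fell (median −3.09), among them PRP3 (−3.09, SE 0.392), EXPA7 (−1.91), SHV2 (26.9-fold lower, 95% interval 9.06 to 132) and LRX1 (23.4-fold lower, 6.33 to 196). Auxin genes rose in 11 of 15 cases and fell in 1 (median 1.33), with the auxin-conjugating WES1 (3.96) and GH3.3 (3.81), IAA19 (2.57) and IAA29 (2.04). Vascular genes rose in 7 of 10 cases (median 1.22), with XCP1 (2.76), SEOR1 (2.02), SUC2 (1.96) and IRX3 (1.42, and −0.10 with library totals only). Salicylic acid, jasmonate and pathogen genes rose in 8 of 15 cases and fell in 2 (median 0.91), with CBP60G (3.12), WRKY33 (2.57), EDS16 (2.23) and MPK3 (2.11). The medians of the auxin (−0.21), vascular (−0.31), pathogen (−0.63), abscisic acid (−0.22) and heat stress transcription factor (−1.25) lists lay below 0 with library totals only. Of 296 genes in the list of cytosolic ribosomal proteins, which was made from annotation and also holds plastid forms such as RPS1 and emb1473, 163 rose and 33 fell (median 0.49, and −1.05 with library totals only), with AT3G14595 (2.35), AT1G64510 (2.28), RPS1 (2.19) and emb1473 (2.17) passing with the smallest adjusted p.

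By camera with the preset correlation 13 of the 24 lists differed from other genes after heat in WT, and 2 kept the call when the correlation was estimated. These were the small heat shock proteins (adjusted p 3.62e-14, and 0.0334 estimated) and the oxidative stress genes (3.09e-08, and 0.00633 estimated). The HSP70, HSP90, HSP100 and co-chaperones list had an adjusted p of 2.63e-19, and adjusted p = 0.0659 with an estimated correlation. Nuclear photosynthesis and carbon fixation genes had 7.01e-13, and adjusted p = 0.192 with an estimated correlation. The lists of abscisic acid and dehydration response (1.65e-05), auxin response and growth (0.00115), vascular tissue markers (0.00687), root hair markers (0.0185) and histone deacetylases (0.0185) each had adjusted p = 0.117 with an estimated correlation. The lists of salicylic acid, jasmonate and pathogen response (0.0185) and of transposable element genes (0.0444) had adjusted p = 0.150 with an estimated correlation. The transposable element call was also lost without WT normal 1 (0.052), WT normal 3 (0.0669), WT heat 1 (0.101) or hd2b hd2c heat 1 (0.0522), with library totals only (0.294), with upper-quartile factors (0.0711) and without a filter on low counts (0.105). The root hair (0.174) and histone deacetylase (0.712) calls were lost with library totals only. Heat stress transcription factors (0.017) had adjusted p = 0.356 with an estimated correlation. Cytosolic ribosomal proteins (1.22e-05) had adjusted p = 0.499 with an estimated correlation, and 0.976 in the other direction with library totals only. The other 11 lists did not pass. In them 4 genes rose and 3 fell of 19 for cell division, 4 and 4 of 12 for the circadian clock, 4 and 13 of 23 for DNA methylation maintenance and heterochromatin, and 8 and 6 of 16 for the unfolded protein response. Likewise 1 rose and 2 fell of 10 for flowering time, 2 and 7 of 14 for other small RNA pathways, 7 and 7 of 17 for ribosome biogenesis, and 7 and 8 of 26 for RdDM. Tissue markers gave 2 and 6 of 14 for root endodermis and uptake, 2 and 2 of 4 for shoot meristem and epidermis, and 0 and 6 of 8 for the stomatal lineage. Adjusted over the list alone, the counts were the same in every list except the unfolded protein response (8 and 7) and root endodermis (1 and 4). Median, mean and test differed in sign for the clock, flowering time and ribosome biogenesis lists. Without hd2b hd2c heat replicate 2, the library that stood apart, 6473 genes rose and 7499 fell.

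In the libraries labelled hd2b hd2c all 17 small heat shock protein genes also rose with heat, and TAS1A fell. APX2 had 0 counts before heat and 7095 after (at least 5820-fold higher). HSP23.6-MITO rose by 13.16 (SE 0.363), ATHSP22.0 by 12.73, HSP17.6A by 12.61, HSP17.6II by 12.51 (SE 0.277) and HSP17.6C by 12.50 (median of the list 11.62), while HSP15.4 (−0.79) and HSP14.7 (−0.14) turned negative with library totals only. Of the HSP70, HSP90, HSP100 and co-chaperone genes 27 of 28 rose (median 4.30), with Hsp70b at 10.37, ROF2 at 9.27 and HSA32 at 7.40. All 26 nuclear photosynthesis genes rose (median 2.83), with LHCB2.1 at 5.75 and LHCB3 at 4.07, and 12 of 13 oxidative stress genes rose, with GolS1 at 8.67 and CAT2 at 4.04. Heat stress transcription factor genes rose in 10 of 21 cases and fell in 4, and HSFA2 rose by 10.91 (SE 0.29), HSFA7A by 8.03, DREB2A by 6.95, HSFB2A by 5.34 and HSFA3 by 1.85 (SE 0.25), while HSFA1E turned to −0.46 with library totals only. TAS1A (−7.03, SE 0.4), AT3G61898 (−5.61), the small RNA source AT1G63130 (−5.25), the F-box genes AT3G18320 (−5.11) and AT5G07610 (−5.01), and TCP3, a leaf growth regulator (−4.98, SE 0.526), fell. NCED3 (3.99), HAI1 (3.31), ABI1 (1.98) and ABF3 (1.80) were among 15 of 19 abscisic acid genes that rose. WES1 (3.70), GH3.3 (3.52), IAA19 (1.89) and PIF4 (0.79) were among 11 of 15 auxin genes that rose, while 2 fell, and PIF4 turned to −0.70 with library totals only. In the histone deacetylase list, which leaves out HD2B and HD2C, all 8 genes that passed rose, including HDA08 (2.65), HDA6 (1.16) and HDT4 (0.36). With library totals only all of these 8 but HDA08 turned negative. AGO4 rose by 1.31 (SE 0.148, adjusted p 6.84e-08), and 9 RdDM genes rose and 5 fell, including NRPD2A (1.60), RDR2 (1.44), RDM1 (1.28), NRPD1A (1.1), AGO6 (0.91), DRM2 (0.83), KTF1 (−1.63), CHR38 (−1.50), chr31 (−1.44), RDM4 (−1.38) and IDN2 (−3.22, SE 0.268). AGO4 (−0.22), AGO6 (−0.52), NRPD1A (−0.34), DRM2 (−0.59), RDM1 (−0.19), SUVH9 (−0.75) and CRT1 (−0.72), or 7 of the 9 that rose, turned negative with library totals only. ONSEN3 rose by 2.96 (SE 0.726) and ONSEN5 was 51.7-fold higher (95% interval 13.4 to 441). PRP3 (−2.53), EXPA18 (−1.93), SHV2 (39.4-fold lower, 6.91 to 1570) and LRX1 (11-fold lower, 2.89 to 92.9) were among 6 of 7 root hair genes that fell. SEOR1 (2.31), SUC2 (2.2) and XCP1 (2.54) were among 8 of 10 vascular genes that rose, and IRX3 turned to −0.073 with library totals only. In total 6058 genes rose and 6380 fell (3391 and 4162 at least 2-fold), with 48.7% of calls increases and a median of −0.12. With library totals only 969 were higher and 15816 lower (5.8%, median −1.56), and with upper-quartile factors 4752 and 8258 (36.5%, median −0.38).

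By camera 11 lists differed from other genes with heat in the libraries labelled hd2b hd2c, and 2 kept the call with an estimated correlation, the small heat shock proteins (adjusted p 7.27e-15, and 0.0289 estimated) and oxidative stress genes (1.72e-08, and 0.00566 estimated). The HSP70, HSP90, HSP100 and co-chaperones list had 1.79e-20, and adjusted p = 0.0565 with an estimated correlation. Nuclear photosynthesis and carbon fixation had 4.39e-13, and adjusted p = 0.204 with an estimated correlation. The lists of abscisic acid and dehydration response (2.46e-05), vascular tissue markers (0.00367) and histone deacetylases (0.0257) had adjusted p = 0.110 with an estimated correlation. Auxin response and growth (0.00329) and root hair markers (0.0428) had adjusted p = 0.168 with an estimated correlation, and heat stress transcription factors (0.00367) had adjusted p = 0.254 with an estimated correlation. Cytosolic ribosomal proteins, of which 155 rose and 43 fell, had 6.61e-05, adjusted p = 0.537 with an estimated correlation, and 0.728 in the other direction with library totals only. Medians turned below 0 with library totals only for the abscisic acid (−0.17), auxin (−0.42), vascular (−0.28), histone deacetylase (−0.83), heat stress transcription factor (−0.70) and ribosomal protein (−1.07) lists. Transposable element genes did not pass (2 rose and 12 fell of 18, adjusted p 0.0579), and passed without hd2b hd2c heat replicate 2 (0.0287) or hd2b hd2c normal 3 (0.0481), with only the groups compared (0.0479) or with a filter of 1 CPM (0.0216), with adjusted p from 0.109 to 0.227 in these fits with an estimated correlation. The root hair call was lost without hd2b hd2c heat 3 (0.0942), with upper-quartile factors (0.089) and with library totals only (0.336), as was the histone deacetylase call with library totals only (0.556). Salicylic acid, jasmonate and pathogen response passed without WT heat 2 (0.0494, and 0.306 with an estimated correlation) or hd2b hd2c normal 3 (0.0479, and 0.2), and with only the groups compared it passed (0.0479, and 0.477), as did the stomatal lineage as lower (0.0479, and 0.227). The other 12 lists did not pass, among them salicylic acid, jasmonate and pathogen response (8 rose, 1 fell), DNA methylation maintenance and heterochromatin (4 and 9), RdDM (9 and 5), stomatal lineage (0 and 4), the clock (5 and 4), cell division (6 and 2) and the unfolded protein response (8 and 7). Flowering time had 1 and 1, other small RNA pathways 3 and 4, ribosome biogenesis 7 and 5, root endodermis and uptake 3 and 6, and shoot meristem and epidermis 2 and 1. Adjusted over the list alone, the counts differed for auxin (12 and 2), the clock (6 and 4), ribosomal proteins (156 and 43), oxidative stress (13 and 0) and ribosome biogenesis (8 and 5).

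The heat effects in the 2 genotypes were close to each other gene by gene. 5477 genes rose in both, among them the small heat shock proteins, Hsp70b, LHCB2.1 and AGO4, against 1877.1 for independent lists of the same sizes, and 5509 fell in both, among them TAS1A, IDN2 and PRP3, against 2221.9. In opposite directions 9 genes were called. Across the 20232 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.89 and a Spearman correlation of 0.915. The slope of hd2b hd2c against WT was 0.922 by total least squares, which allows for spread in both and is not an ordinary regression slope. The heat effects share no libraries, but both come from 1 fit with a shared estimate of spread per gene. Calls in the 2 lists are therefore not independent, and the values for independent lists are a reference only. With library totals only 852 genes were higher in both and 15142 lower.

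**Figure D3:**
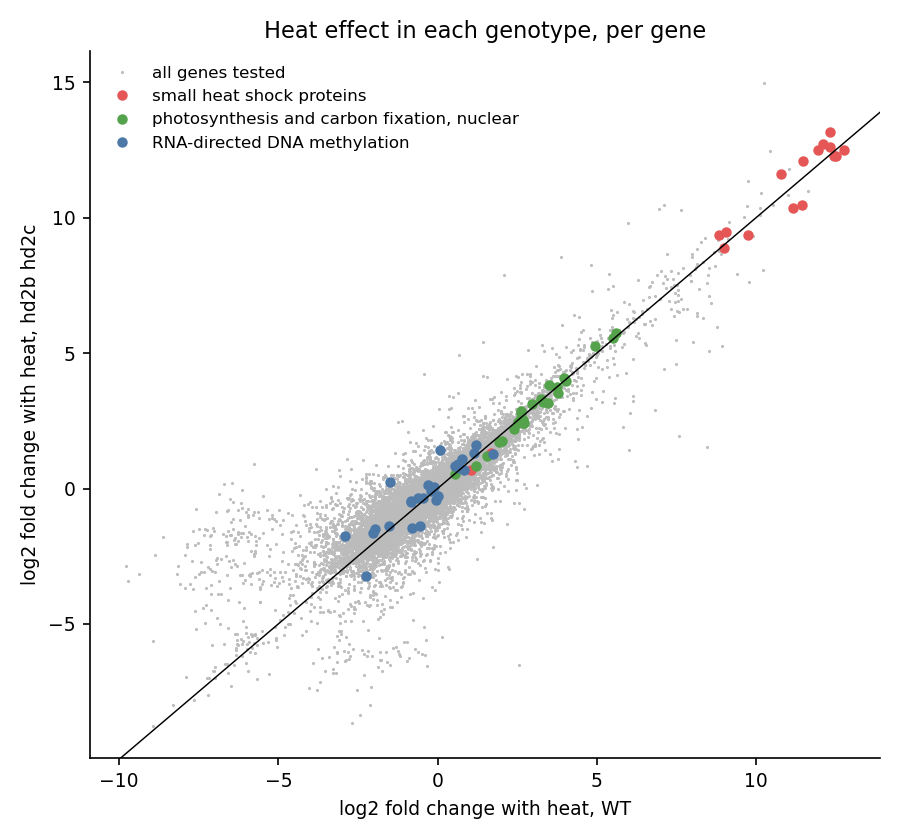
Log2 fold change with heat in WT (x axis) and in the libraries labelled hd2b hd2c (y axis) for each of 20232 tested genes, with 3 gene lists coloured and a line of equal effect. Small heat shock proteins lie at the upper right, with medians of 11.45 and 11.62, while RdDM genes lie on both sides of 0, and with library totals only most of those that rose turn negative.

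At normal temperature a small set of genes differed between WT and the libraries labelled hd2b hd2c, in which HD2C counts do not bear out the label. AT3G01345, of unknown function, fell from 207 to 1.93 CPM, or −6.74 (SE 0.203, adjusted p 2.54e-16). FLC, a repressor of flowering, fell by 1.95 (SE 0.202, adjusted p 2.87e-06), and so did the glycine-rich protein gene AT2G05510 (−2.00), AT2G32240 (−1.98), AT4G05631 (−2.13) and AT3G56410 (−1.94). The pseudogene AT2G35570 had 2 counts in WT and 544 in hd2b hd2c (248-fold higher, 95% interval 68.4 to 2050). The transporter gene AT2G04050 rose by 6.04 (SE 0.667, adjusted p 9.24e-06), the NAC transcription factor gene NAC044 by 4.18 (SE 0.456, adjusted p 6.89e-06) and the suffixed pseudogene AT5G35935.1 by 3.68 (SE 0.294). AT5G51190, of the ethylene response factor family, rose by 2.87 (SE 0.28, adjusted p 1.28e-06) and STZ, a stress-induced zinc finger repressor, by 2.73 (SE 0.294, adjusted p 0.000178). Of 19 abscisic acid and dehydration genes 7 rose and none fell (median 0.30), with the cold and drought genes KIN1 (1.48) and COR15A (1.05, SE 0.168), HAI1 (1.15) and NCED3 (0.90). Of 28 genes for HSP70, HSP90, HSP100 and co-chaperones 5 fell and none rose (median −0.28), with BAG6 (−1.57, SE 0.236, adjusted p 0.000497), ROF2 (−1.38), Hsp70b (−0.85) and HSP90.1 (−0.79). Of 12 clock genes 3 fell and none rose (median −0.38), namely PRR9 (−2.71, SE 0.681, adjusted p 0.029), PRR7 (−0.79, adjusted p 0.0405) and GI (−0.40, adjusted p 0.0353). Of 23 genes of DNA methylation maintenance and heterochromatin 3 fell and none rose (median −0.11), the demethylase genes DME (−0.82, SE 0.141, adjusted p 0.00156) and IBM1 (−0.82, a histone demethylase) and the methyltransferase gene CMT2 (−0.55). Of 26 RdDM genes KTF1 (−1.25) and NRPD1B (−0.69) fell, and AGO4 did not pass (−0.21, SE 0.145, adjusted p 0.609). HDA3, listed as HD2A and another gene of the HD2 family, rose (0.61). HSFA7A (−1.02, SE 0.161, adjusted p 0.000699) and DREB2A (−0.70) fell, and no small heat shock protein gene passed (median −0.27). IAA29 (0.79) was the auxin gene that rose of 15. Of 296 genes in the list of cytosolic ribosomal proteins 6 rose (median 0.13), with AT5G25230 (2.17), AT2G40010 (1.28), AT5G39850 (0.84) and AT5G08180 (0.51). That list was matched by annotation words, so a member need not be a ribosomal protein. In total 198 genes rose and 338 fell by edgeR's quasi-likelihood test (100 and 106 at least 2-fold), so 36.9% of calls were increases, and the median of all genes was 0. With library totals only the calls were 74 higher and 28 lower (72.5% higher), with only the groups compared 592 and 1063, without a filter on low counts 301 and 493, and at an adjusted p under 0.01 they were 108 and 125. Of 36 called genes under the naming rule 17 kept call and direction in every alternative, including AT3G01345, FLC, AT2G35570, NAC044, AT5G51190, STZ, COR15A, KIN1, HAI1, BAG6 and HSFA7A, while PRR9, PRR7 and NRPD1B lost the call without any 1 of the 6 libraries compared, GI and CMT2 without any of 5 of them and KTF1 without any of 4. Leaving out 1 library moved the counts to 101 and 174 (WT normal 1), 110 and 106 (WT normal 2), 129 and 159 (hd2b hd2c normal 1), 119 and 154 (hd2b hd2c normal 2), 148 and 146 (hd2b hd2c normal 3) and 408 and 653 (hd2b hd2c heat 2, which shares the estimate of spread).

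By camera 7 lists differed between the genotypes at normal temperature, and none kept the call with an estimated correlation. The HSP70, HSP90, HSP100 and co-chaperones list was lower (adjusted p 1.58e-08), as was root hair markers (0.0469, median −0.81, none called), each with adjusted p = 0.303 with an estimated correlation. The clock list was lower (1.04e-06), with adjusted p = 0.184 with an estimated correlation. DNA methylation maintenance and heterochromatin was lower (0.0469) and abscisic acid and dehydration response higher (0.00612), each with adjusted p = 0.315 with an estimated correlation. Auxin response and growth was higher (0.00829), with adjusted p = 0.303 with an estimated correlation, and cytosolic ribosomal proteins were higher (1.09e-06), with adjusted p = 0.458 with an estimated correlation. Adjusted over the list alone, 10 genes fell in the HSP70 list, 7 in the clock list, 5 in DNA methylation maintenance and none in root hair, while 8 rose and 2 fell in abscisic acid, 4 rose in auxin and 5 in ribosomal proteins. By the same count 2 rose and 3 fell in RdDM (adjusted p of the list 0.196), 2 rose in histone deacetylases (0.0977), and 1 rose and 3 fell in heat stress transcription factors (0.263), adjusted over the list alone. Of the other lists, which did not pass, oxidative stress had 1 gene that rose and 1 that fell (1 and 3 adjusted over the list alone), the unfolded protein response 1 and 2 (1 and 3), and ribosome biogenesis 2 that rose (3). Flowering time had 1 that fell, other small RNA pathways 1 that fell, pathogen response 1 that rose and transposable element genes 1 that rose, with the same counts adjusted over the list alone. Cell division and shoot meristem had no called gene and 1 that rose adjusted over the list alone, and the lists of photosynthesis, small heat shock proteins, root endodermis, stomatal lineage and vascular markers had none by either count. Median, mean and test differed in sign for the unfolded protein response and stomatal lists. The DNA methylation maintenance call held without WT normal 3 or hd2b hd2c normal 1 and was lost without each of the other 10 libraries (adjusted p 0.0506 to 0.124), with library totals only (0.118), upper-quartile factors (0.052), a filter of 1 CPM (0.0524), a replicate block (0.0791) or only the groups compared (0.113). With fry the clock list kept the call and the other 6 lost it. The root hair call was lost without WT normal 1 (0.127), WT normal 3 (0.0513), WT heat 3 (0.056), hd2b hd2c normal 1 (0.0855), hd2b hd2c normal 2 (0.0529) or hd2b hd2c heat 2 (0.0525) and with a filter of 1 CPM (0.0857). Without WT normal 1 the abscisic acid (0.0595) and auxin (0.127) calls were lost, the auxin call without hd2b hd2c normal 2 (0.0529) or with library totals only (0.0573), and the abscisic acid call with only the groups compared (0.101). Small heat shock proteins passed as lower without WT normal 1 (0.0159, and 0.381 with an estimated correlation) or WT normal 3 (0.041, and 0.433), and histone deacetylases as higher without hd2b hd2c normal 1 (0.0289, and 0.291 with an estimated correlation). Ribosome biogenesis (0.0246) and cell division (0.0495) passed as higher without WT normal 2, each with adjusted p = 0.302 with an estimated correlation.

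After heat AT3G01345 and FLC were again lower than in WT in the libraries labelled hd2b hd2c, in which HD2C was higher. AT3G01345 (−6.87, SE 0.273, adjusted p 1.11e-13), FLC (−2.16, SE 0.233, adjusted p 7.32e-06), AT2G05510 (−2.11), the cysteine protease gene AT4G11320 (−1.79, SE 0.141) and AT4G14060 (−1.70) fell. The RING finger gene AT5G60250 rose by 4.38 (SE 0.467, adjusted p 6.31e-06), AT2G01023 by 4.30 (SE 0.431), AT5G35935.1 by 3.09, AT2G01008 by 2.61 and ACC2, a plastid acetyl-CoA carboxylase gene, by 2.5 (SE 0.23, adjusted p 6.94e-07), beside CTR1 (2.63). ACC2 has a close paralogue, ACC1, so its counts are uncertain. Of 28 genes for HSP70, HSP90, HSP100 and co-chaperones 4 fell and none rose (median −0.18), namely BAG6 (−0.89, SE 0.198, adjusted p 0.0177), HSP90.1 (−0.67), Hsp70b (−0.62) and Hop2 (−0.62). Of 17 genes of ribosome biogenesis 3 rose and none fell (median 0.23), namely NUC-L2, a nucleolin gene (1.40, SE 0.32, adjusted p 0.0199), FIB2, a fibrillarin gene (0.70, SE 0.123, adjusted p 0.00253), and PES (0.47). Of 26 RdDM genes IDN2 fell (−1.32, SE 0.31, adjusted p 0.0232), and AGO4 did not pass (−0.03, SE 0.146, adjusted p 0.95). HDT4, another gene of the HD2 family, rose (0.69), HSFA3 rose (1.91) and HSP15.4 fell (−0.80) as the called members of the histone deacetylase, heat stress transcription factor and small heat shock protein lists. In total 321 genes rose and 238 fell by edgeR's quasi-likelihood test (89 and 57 at least 2-fold), so 57.4% of calls were increases, and the median of all genes was 0.005. With library totals only 39 were higher and 14 lower (73.6% higher), with only the groups compared 45 and 34, with a replicate block 201 and 139, with DESeq2 517 and 419, without a filter on low counts 459 and 392, and at an adjusted p under 0.01 there were 86 and 58. Of 22 called genes under the naming rule 12 kept call and direction in every alternative, including AT3G01345, FLC, CTR1, ACC2, FIB2 and HSFA3, while BAG6, HSP90.1 and IDN2 lost the call without WT heat 1, WT heat 2 or hd2b hd2c heat 1 and NUC-L2 without WT heat 1 or hd2b hd2c heat 1. Leaving out 1 library moved the counts to 171 and 116 (WT heat 1), 136 and 81 (WT heat 2), 197 and 176 (WT heat 3), 99 and 53 (hd2b hd2c heat 1), 195 and 226 (hd2b hd2c heat 3) and 218 and 156 (hd2b hd2c normal 2). Without hd2b hd2c heat 2, the library that stood apart, 732 rose and 703 fell.

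By camera 2 lists differed between genotypes after heat, and none kept the call with an estimated correlation. Ribosome biogenesis was higher (adjusted p 0.0252), with adjusted p = 0.694 with an estimated correlation, and lost the call without WT heat 3 (0.111) or hd2b hd2c heat 3 (0.224). The HSP70, HSP90, HSP100 and co-chaperones list was lower (0.0289), with adjusted p = 0.773 with an estimated correlation, and lost the call without WT heat 1 (0.114), WT heat 2 (0.0556), hd2b hd2c heat 1 (0.111) or hd2b hd2c heat 2 (0.206) and with library totals only (0.0755). With fry neither passed (0.0788 and 0.195). In these lists 4 ribosome biogenesis genes rose, and 1 HSP70 gene rose and 10 fell, adjusted over the list alone. Photosynthesis genes did not pass (median −0.16, adjusted p 0.0896) and passed as lower without hd2b hd2c heat 2 (2.91e-11, and 0.452 with an estimated correlation), without WT heat 1 (0.0166, and 0.751) and with library totals only (0.00863, and 0.957). Other small RNA pathways did not pass (1 gene rose, median 0.29, 0.0896) and passed as higher without hd2b hd2c heat 2 (0.0288, and 0.324 with an estimated correlation). Ribosomal proteins did not pass (9 genes rose and 2 fell, 0.0897, and 11 and 4 adjusted over the list alone) and passed as higher without WT heat 3 (0.00521), hd2b hd2c heat 1 (0.00833) or hd2b hd2c heat 3 (0.00186) and with library totals only (0.00863), with adjusted p from 0.761 to 0.957 in these fits with an estimated correlation. Of the other lists, which did not pass, abscisic acid had 5 genes that rose and 2 that fell (7 and 4 adjusted over the list alone), flowering time 1 and 1 (1 and 2), cell division 1 that rose (3), the clock 1 that rose (2), the unfolded protein response 1 that rose (2) and auxin 1 that fell (1 and 2). Adjusted over the list alone, 3 histone deacetylase genes rose, 2 heat stress transcription factor and 2 transposable element genes rose, 3 small heat shock protein genes fell, 1 oxidative stress gene rose and 1 fell, 1 pathogen response gene fell and 2 genes of DNA methylation maintenance fell. RdDM (1 that fell) and shoot meristem (1 that rose) had the same counts adjusted over the list alone, and root endodermis, vascular, root hair and stomatal markers had no called gene by either count. Median, mean and test differed in sign for auxin, heat stress transcription factors, RdDM, pathogen response, stomatal lineage and transposable element genes, and the medians of heat stress transcription factors, root hair markers and transposable element genes turned sign with library totals only. Between the genotype effects at the 2 temperatures, which share no libraries, 60 genes were called higher in both, among them HD2C, ACC2 and AT5G35935.1, against 3.1 for independent lists, and 64 lower in both, among them HD2B, FLC, AT3G01345 and BAG6, against 4. Both genotype effects come from 1 fit with a shared estimate of spread per gene, so the values for independent lists are a reference only. With library totals only the genes called higher and lower in both were 20 and 9, and 114 were lower in both with DESeq2 and 108 without a filter on low counts. Called higher and lower in both were 32 and 39 without WT normal 1, 39 and 36 without WT heat 1, 38 and 33 without WT heat 2, 39 and 40 without hd2b hd2c normal 1, 38 and 39 without hd2b hd2c normal 2, 34 and 29 without hd2b hd2c heat 1, and 97 and 133 without hd2b hd2c heat 2. The count called lower in both was 38 without WT normal 2 and 40 without hd2b hd2c normal 3. The log2 fold changes had a Pearson correlation of 0.257 across the 20232 genes, which are not independent replicates, and 0.57 across the 969 called in either.

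**Figure D4:**
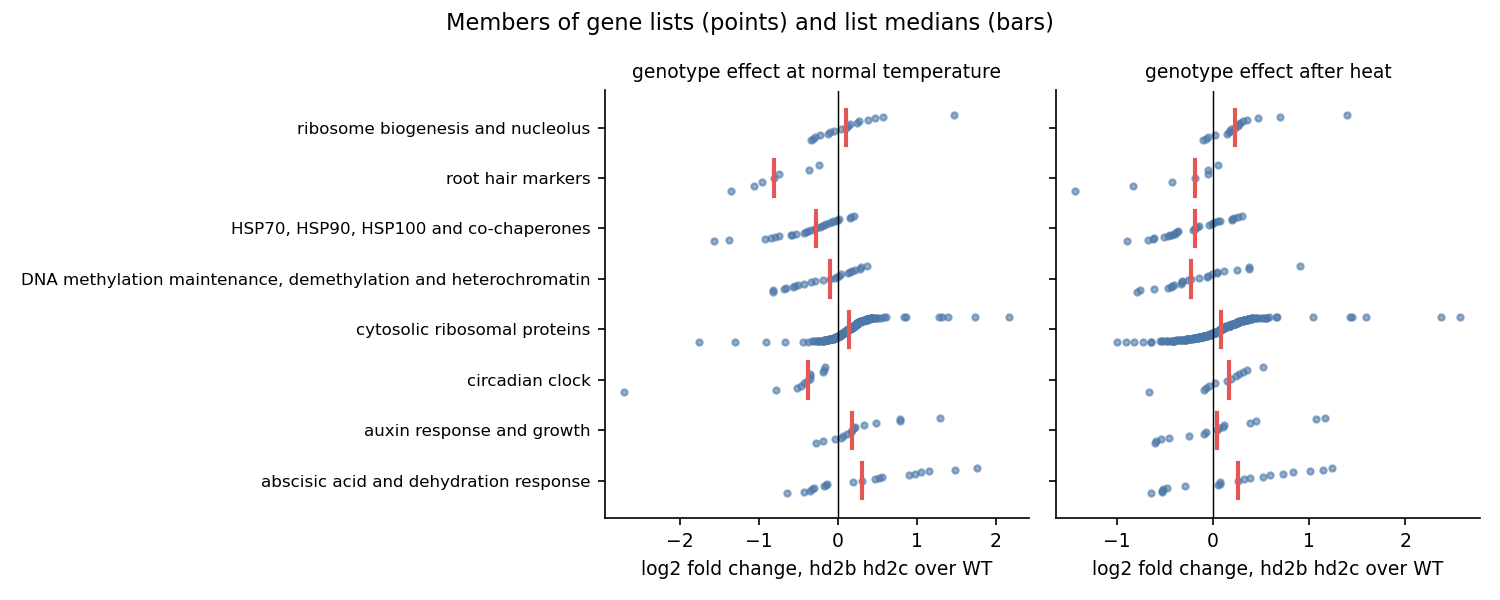
Log2 fold change of the libraries labelled hd2b hd2c over WT for members (points) of the lists that camera called in a genotype comparison, with list medians (bars), at normal temperature and after heat. The HSP70, HSP90, HSP100 and co-chaperones list has a median of −0.28 at normal temperature and −0.18 after heat, and with library totals only the root hair median after heat turns positive.

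The interaction asked which genes responded to heat differently in WT and in the libraries labelled hd2b hd2c, in which HD2C was higher. AT5G51190 had an interaction of −3.61 (SE 0.37, adjusted p 1.44e-05), STZ −3.25 (SE 0.382, adjusted p 0.00199), the deadenylase gene CAF1a −3.10, the mitochondrial carrier gene DIC2 −2.95 (SE 0.336, adjusted p 6.11e-05), the pathogen response gene SIB1 −2.59 and the calcium-binding gene AT4G27280 −2.57 (SE 0.297, adjusted p 0.000442), beside HD2B (−1.40). CTR1 had 2.43. AT3G23470 had 6.93, a fitted value that depends on the prior count because WT heat had 0 counts. The suffixed pseudogene AT2G12490.1 (2.32), the DnaJ gene AT1G74250 (1.94), AT4G38060 (1.45) and SNL6 (1.44) had positive values as well. The clock gene GI (0.71, SE 0.145, adjusted p 0.0273) and HSFA7A (1.01, SE 0.208, adjusted p 0.0284) also passed. AGO4 did not pass (0.18, SE 0.206, adjusted p 0.864), nor did any RdDM or small heat shock protein gene. UPL2, a ubiquitin ligase gene, and ERF6, an ethylene response factor gene, were called in opposite directions at the 2 temperatures and were chosen after their values were seen. UPL2 was −0.45 at normal temperature and 0.57 after heat (interaction 1.02, adjusted p 0.00443), and ERF6 1.59 and −0.77 (−2.36, adjusted p 0.000603). By edgeR's quasi-likelihood test 30 genes passed with a positive and 38 with a negative interaction (19 and 34 at least 2-fold), so 44.1% were positive, and with library totals only 2 and 8 (20%). The balance turned with DESeq2, to 116 positive and 78 negative (59.8%), and without a filter on low counts, to 93 and 87 (51.7%), while a replicate block gave 15 and 32 and an adjusted p under 0.01 gave 4 and 12. Of 15 called genes under the naming rule CTR1, AT5G51190, STZ, DIC2 and AT4G27280 kept call and direction in every alternative. Leaving out 1 library gave 8 and 14 (WT normal 1), 5 and 11 (WT normal 2), 16 and 27 (WT heat 2), 5 and 16 (WT heat 3), 15 and 39 (hd2b hd2c normal 1), 5 and 13 (hd2b hd2c normal 2), 19 and 29 (hd2b hd2c normal 3), 8 and 16 (hd2b hd2c heat 1) and 17 and 50 (hd2b hd2c heat 3). Without hd2b hd2c heat 2, the library that stood apart, 172 and 167 genes passed.

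The clock list had a positive interaction as a set (median 0.65, adjusted p 7.98e-06 by camera, 12 genes), with adjusted p = 0.234 with an estimated correlation and 0.0604 with fry. GI was the member called over all genes, and adjusted over the list alone 6 were positive. The other 23 lists did not pass. Over all genes 1 ribosomal protein gene and HSFA7A were positive, and 1 pathogen response and 1 oxidative stress gene negative. Adjusted over the list alone, 3 auxin, 2 pathogen response and 1 abscisic acid genes were negative, 1 gene each of other small RNA pathways, the unfolded protein response, ribosomal proteins and flowering time was positive, 2 heat stress transcription factor genes were positive, oxidative stress had 2 positive and 1 negative, shoot meristem had 1 and 1, and the rest had none. Without hd2b hd2c heat 2 the lists of ribosomal proteins (8.57e-08, and 0.623 with an estimated correlation) and photosynthesis (5.45e-08, and 0.617) passed with a negative interaction and the HSP70 list (0.0176, and 0.808) and other small RNA pathways (0.0173, and 0.294) with a positive interaction. Ribosomal proteins also passed without WT heat 1 (0.0277, and 0.922 with an estimated correlation) or hd2b hd2c normal 3 (0.035, and 0.891). Without WT normal 3 the HSP70 list (0.0329, and 0.961 with an estimated correlation) and, with a negative interaction, auxin (0.0165, and 0.403) passed. Median, mean and test differed in sign for flowering time, histone deacetylases, oxidative stress, root endodermis, shoot meristem, small heat shock proteins and transposable element genes.

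Loci of the transposable element list made up a smaller share of counts after heat in both genotypes. Shares of counts are on the scale of library totals, on which 16005 genes were lower and 1031 higher with heat in WT and the list of transposable element genes did not pass (adjusted p 0.294). The 64 loci of that list, matched by words in the annotation, took 0.0586% ± 0.00250 of counts in WT normal and 0.00893% in WT heat. They took 0.0638% ± 0.00609 in hd2b hd2c normal and 0.0107% ± 0.000617 in hd2b hd2c heat (SD, n = 3). Each heat comparison had p 0.1 by an exact two-sided permutation test, the smallest that 3 against 3 libraries allow (adjusted p 0.2 over 24 tests), and genotype had p 0.3 at normal temperature and 0.1 after heat. The wider class of 3909 suffixed pseudogene loci, added after the identifiers were seen, took 0.233%, 0.0395%, 0.232% and 0.0530% in WT normal, WT heat, hd2b hd2c normal and hd2b hd2c heat. Of its 141 tested loci 15 rose and 67 fell with heat in WT (median −1.09) and 16 rose and 61 fell in hd2b hd2c (median −0.75). After heat 7 of them rose and 1 fell between the genotypes (median 0.23, unadjusted camera p 0.00261, and 0.0597 with an estimated correlation), and at normal temperature 3 rose and 5 fell. The 8 ONSEN copies had 9 counts in all in WT normal, 128 in WT heat, 14 in hd2b hd2c normal and 95 in hd2b hd2c heat. Among loci kept silent by DNA methylation, SDC had 6, 2 and 7 counts in WT normal and 12, 16 and 18 in hd2b hd2c normal, FWA had at most 6 in any library, and MU1 and EVD had at most 2. These counts are not scaled for depth, and WT normal replicate 2 had 10443494 counts against 16844188 to 22083518 in the other normal libraries. No call between the genotypes is given for SDC. After heat SDC had 6, 0 and 2 counts in WT and 8, 0 and 2 in hd2b hd2c. QQS had 18 to 27 counts in WT normal and 14 to 49 in hd2b hd2c normal. Seed storage genes had 0 members that passed the filter. As shares of counts, photosynthesis genes took 9.03%, 24.4%, 8.31% and 21.7%, and small heat shock proteins 0.00637%, 1.62%, 0.00532% and 1.63% in WT normal, WT heat, hd2b hd2c normal and hd2b hd2c heat, each with p 0.1 for heat by the exact permutation test.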

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

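The tests of the HD2C neighbourhood, of exchanged or wild-type libraries, of the depth of WT normal replicate 2 and of other splits of the libraries were chosen only after the results were seen. The tests on hd2b hd2c heat replicate 2 and on the touch and wound response genes were written before their values were seen, after the patterns had been noticed.

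Every result here is a difference between the heat effects of the genotypes, tested as an interaction. Directions rest on the label hd2b hd2c, which HD2C counts do not bear out. The interaction passed with a positive value for 30 genes and a negative value for 38. The positive values named were AT3G23470 (6.93, fitted against a group at 0), CTR1 (2.43), AT2G12490.1 (2.32), AT1G74250 (1.94), AT4G38060 (1.45), SNL6 (1.44), HSFA7A (1.01) and GI (0.71). The negative values named were AT5G51190 (−3.61), STZ (−3.25), CAF1a (−3.10), DIC2 (−2.95), SIB1 (−2.59), AT4G27280 (−2.57) and HD2B (−1.40). The clock list had a median of 0.65, and its call was lost with an estimated correlation (adjusted p = 0.234) and with fry (0.0604). Of 100 splits of the libraries, 2 gave at least the real 68 called genes, the real split included, and the highest of the others gave 192. The 83 splits that mix the genotypes at both temperatures carry genotype differences in their spread and gave 0, so the share is low by design and leaves chance open. The split with 192 keeps the normal libraries apart by genotype and joins hd2b hd2c heat replicate 2 with WT heat replicates 2 and 3, so it holds the genotype difference at normal temperature and points to a structure of the samples. Without WT normal 1, WT normal 2 or WT heat 3 the counts were 8 and 14, 5 and 11, and 5 and 16, and without hd2b hd2c heat 2 they were 172 and 167.

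HD2C and genes beside it were higher in the libraries labelled hd2b hd2c. Wild-type plants alone in a library labelled hd2b hd2c are argued against, since 0 of the 6 lay within the WT range of HD2C, while a share of wild-type plants within libraries was not tested and stays open, with HD2B at 23.8 CPM against 40.0 in WT at normal temperature. An exchange of the genotype labels of all libraries stays open, since 1 of the 2 genes of the label, HD2B, was lower in the libraries labelled hd2b hd2c and HD2C was higher. Of the 8 nearest tested neighbours of HD2C 4 were called higher, which 0.0198% of windows elsewhere reached (4 of 20157), so the data are consistent with a local effect at the HD2C locus. Read-through from an insertion and a chromosome rearrangement may both give such a pattern, and counts per gene do not separate them or show whether the HD2C transcript is complete.

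hd2b hd2c heat replicate 2 differed from the other libraries of its group. Replicate 1 thinned to 6861443 counts had a chi-square per gene of 7.09 against replicate 3, and 14.3 before thinning. Replicate 2 had 57.4 against replicate 3, with ribosomal RNA left out of all these values. Fewer counts lower this measure, so the thinned library could not have reached that value. Lower depth thus does not account for the high chi-square, while its part in the lower Spearman correlation was not tested. Ribosomal RNA reads alone are argued against by that same 57.4, which fell from 151 with them and stayed above the 19.6 of the highest pair in the other 3 groups. A loss of long transcripts is consistent with the correlation of −0.394 between its deviation and exon length across 9537 genes, with medians of 0.39 for exon lengths under 1000 nt and −0.24 over 3000 nt. WT heat replicate 3 had −0.345, so the correlation alone does not set the library apart, and no biological explanation was tested because the group has a single label.

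Of the 38 genes with a negative interaction 33 were called higher at normal temperature. The interaction subtracts that difference from the one after heat, so this share is largely set by how the genes were chosen. For the 33 genes a difference was present without heat. This set of 33 genes includes STZ (2.73 at normal temperature), ERF6 (1.59), ERF104 (0.76), MYB77 (1.36), SZF1 (1.26), WRKY70 (2.38) and ACS6 (1.54). Of these 33 genes 28 kept the call at normal temperature without WT normal replicate 2, the shallowest WT normal library. The 28 are no independent check, since the set was chosen by calls from the same libraries. The other 5 cannot decide the part of that library, since leaving out any other library of this comparison also lowered the total of calls. Handling of the seedlings before harvest may contribute, since 18 rapid touch and wound response genes had a median of 0.758 at normal temperature (8 called higher, camera p 1.12e-13, and 0.0046 with an estimated correlation). The group means of these genes differed by 0.739 and libraries within a group by up to 0.668, so handling and genotype cannot be told apart. Of these 18 genes 3 belong to the set, and the 15 outside it had a median of 0.685. After heat the 18 genes had a median of −0.336 between the genotypes and none was called (camera p 0.0103, and 0.216 with an estimated correlation). With heat in WT their median was 1.59, with 16 called higher and 1 lower.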

How the results depend on the processing

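Leaving out ribosomal RNA features, leaving out libraries outside a comparison, an estimated correlation for lists that passed under an alternative alone, and the leave-outs behind shared calls, the heat correlation and transposable element shares were chosen only after the data were seen. The other alternatives were fixed before the data were examined. The alternatives that keep only nuclear genes or nuclear counts were not run, because the table holds no organelle genes, and an organelle share could not be computed.

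Of 268 named gene results all kept call and direction with RLE factors or without ribosomal RNA, 266 did with DESeq2, 263 without a filter, 258 with upper-quartile factors and 237 of 249 with only the groups compared, and none of these reversed. With library totals only 188 kept the call, 45 lost it and 35 reversed. Without hd2b hd2c heat replicate 2, 266 kept it, and without any other library between 240 and 260 did. Of 34 list calls 4 held with an estimated correlation and 25 with fry.

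Library totals give lower values after heat, because TMM factors were 1.619 to 1.856 in normal and 0.424 to 0.744 in heat libraries. With them calls were 1031 higher and 16005 lower for heat in WT, 969 and 15816 for heat in hd2b hd2c, 74 and 28 for genotype at normal temperature, 39 and 14 for genotype after heat and 2 and 8 for the interaction. Shared heat calls were 852 and 15142 and shared genotype calls 20 and 9. HD2B at normal temperature was −0.69 and did not pass. Log2 fold changes that reversed in WT were HD2B −0.43, HD1 −0.62, HDA6 −0.41, HDA2 −0.63, HDA15 −1.06, SRT2 −0.68, HDA3 −0.83, IRX3 −0.10, AGO4 −0.39, NRPD1A −0.75, NRPD2A −0.32, DRM2 −0.99, SUVH9 −0.69, CRT1 −0.84, HSP15.4 −0.48 and HSFA1E −0.44. In hd2b hd2c they were PIF4 −0.70, HD1 −0.61, HDA6 −0.32, HDA15 −0.69, HDA2 −0.62, SRT2 −0.48, HDA3 −0.98, HDT4 −1.15, IRX3 −0.073, AGO4 −0.22, AGO6 −0.52, NRPD1A −0.34, DRM2 −0.59, RDM1 −0.19, SUVH9 −0.75, CRT1 −0.72, HSP15.4 −0.79, HSP14.7 −0.14 and HSFA1E −0.46. Cytosolic ribosomal proteins turned lower as a list (adjusted p 0.976 in WT and 0.728 in hd2b hd2c). Which scale is right was not tested, since total RNA per seedling is not known.

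For the other settings the cause was not tested. DESeq2 called 517 and 419 for genotype after heat, 116 and 78 for the interaction and 114 lower in both genotype comparisons. Without a filter 301 were higher for genotype at normal temperature, 392 lower after heat, 93 and 87 passed in the interaction and 108 were lower in both. Fits of only the groups compared gave 592 and 1063 at normal temperature and 45 and 34 after heat, where the spread comes from 6 libraries. Mean Spearman correlations within groups were 0.987 to 0.99 in normal and 0.961 to 0.981 in heat libraries, so the spread was unequal. The main fit shares 1 estimate of spread per gene. Its similar totals of 536 and 559 genotype calls therefore do not show genotype effects of similar extent at the 2 temperatures. The stricter thresholds give fewer genes by construction. At an adjusted p under 0.01 counts were 108 and 125, 86 and 58, and 4 and 12 for the genotype comparisons and the interaction. At a fold of at least 2 they were 3626 higher in WT, 3391 and 4162 in hd2b hd2c, 100 and 106 at normal temperature, 89 and 57 after heat and 19 higher in the interaction. Lists called with an estimated correlation were 2 and 2 for heat in WT and in hd2b hd2c and 0 in the other 3 comparisons. With fry, which asks another question, they were 20 for heat in hd2b hd2c, 1 for genotype at normal temperature and 0 in the last 2. The correlation of the heat effects was 0.904 over called genes only.

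Leaving out each library, which leaves fewer samples, gave 101 to 408 higher and 106 to 653 lower for genotype at normal temperature, 99 to 732 and 53 to 703 after heat, and 5 to 172 and 11 to 167 for the interaction, the highest each without hd2b hd2c heat 2. Lists called ranged over 4 to 8, 1 to 3 and 1 to 5 for these comparisons. Shared genotype calls ranged from 32 to 97 higher and 29 to 133 lower, and the heat correlation from 0.856 to 0.888.

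With the replicate number as a block, calls were 201 and 139 for genotype after heat and 15 and 32 for the interaction, and 255 of 268 named results and 33 of 34 list calls kept their call. The numbers do not pair the libraries, since correlations of 18 same-number pairs ran from −0.132 to 0.146 and 0 of 12 libraries was closest to its own number in every other group.

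Depth limits what can be said of genes with few counts, such as single ONSEN copies, MU1 and EVD.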

Other observations

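The tests of harvest time, of linkage to HD2B and of other splits of the libraries were chosen only after the results were seen. The genes named here were chosen after their values were seen, and directions rest on the label hd2b hd2c, which HD2C counts do not bear out.

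Several genes differed between the genotypes at both temperatures. NUC-L2, a nucleolin gene that plants use less than its paralogue, rose by 1.48 at normal temperature (SE 0.276, adjusted p 0.00313 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and by 1.40 after heat. ACC2 rose by 1.48 (SE 0.184, adjusted p 4.24e-05) and by 2.5 after heat. COR15A rose by 1.05 and by 1.24 (SE 0.172, adjusted p 0.000257). GMI1, induced by DNA breaks, rose by 2.03 (SE 0.275, adjusted p 0.000117) and by 2.08 (SE 0.323, adjusted p 0.00083), and NAC044 by 4.18 and 3.51. CBF2, a cold response factor gene, rose by 2.31 (SE 0.204, adjusted p 2.59e-07) and by 0.66 (adjusted p 0.0161). WRKY70 rose by 2.38 (SE 0.281, adjusted p 2.32e-05) and did not pass after heat (0.45). AT2G35570 was higher after heat by 5.44.

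Other splits of the 6 libraries of a comparison into 3 and 3 make 10 splits, too few for a share under 0.05. In heat in WT the real split called 13315 genes and the highest other 0, and in heat in hd2b hd2c 12438 and 0. For genotype at normal temperature the real split called 536 and the highest other 1, and for genotype after heat 559 and 158. In each comparison 1 of the 10 splits, the real one, reached the real count. Every other split mixes the real groups and carries their difference in its spread. Low counts in those splits are therefore largely set by design and leave chance open.

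A DNA damage response is a candidate explanation for the higher NAC044 and GMI1. Of 13 other DNA damage response genes the median was 0.305 at normal temperature, and the list had p 0.0249 by camera with an estimated correlation, while no member was called on its own over all genes. After heat their median was 0.14 (camera p 0.456). The test leaves open what would cause such a response.

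Another time of harvest may underlie the lower clock genes at normal temperature. The 7 evening genes had a median of −0.36 (SE 0.06) and the 4 morning genes −0.48 (SE 0.71). All 12 clock genes lay below 0 (−2.71 to −0.17), which goes against a shift that moves morning and evening genes in opposite directions. The morning median was not below 0 by more than its SE, so harvest time and genotype cannot be told apart.

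Linked variation around HD2B could place genes called in both genotype comparisons near that locus. Within 2 Mb of HD2B 8 of 761 tested genes were called in both, and 11.5% of windows elsewhere held as many (median 4, of 126 in all), so this cannot be told apart from the spread of such genes over the genome. Around HD2C 3 of 705 tested genes were called in both and 74.8% of windows held as many. This argues against linked variation within 2 Mb of HD2C as the source of most of the 126 shared calls. A window of that width cannot show linked variation that touches few genes, which stays open.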
